A study of Mus musculus with 12 samples.

How the data were processed

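RNA of mouse splenic B cells was measured on 12 Affymetrix Mouse Genome 430 2.0 arrays, in 6 groups of 2: control, Jmjd2a-depleted and Jmjd2c-depleted cells at day 1 and at day 3. The labels describe total RNA extracted with TRIzol and biotin-labelled cRNA. They speak of siRNA in some places and of virus carrying shRNA in others, and the descriptions of both day 3 control arrays are alike while their titles number them as replicates. A day 0 mentioned for the series was not analysed here. The probe set values were log2 values deposited by the authors, and the normalization behind them is not given in the sources used here. The median of the probe-set means was 5.22. Array values carry no read depth, so the precision of a value comes from the spread between arrays. Of 45101 probe sets, 64 control probe sets were left out and 45037 were tested. Of these, 34945 named 1 gene, 932 named several and 9160 named none, and 18193 genes had at least 1 probe set of their own. Gene symbols were checked against the annotation of assembly GRCm38.p6, which was used for symbols only, and 0 were updated.

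One linear model with 6 group means was fitted to the deposited values in limma 3.58.1 (R 4.3.3), with empirical Bayes moderation and an intensity trend of the prior variance. It left 6 residual degrees of freedom, to which the prior added 5.85. The contrasts were each label against control on its day, day 3 against day 1 for control and for each label, Jmjd2a against Jmjd2c on each day, and the day 3 difference minus the day 1 difference for each label. P-values were adjusted by Benjamini and Hochberg over all probe sets of a contrast, and an adjusted p under 0.05 was called past the test. Standard errors and 95% intervals are those of the moderated model. For comparisons against shared controls, the correlation and covariance of the 2 contrasts were set beside simulated groups without a difference. Replicate pairing by number was checked in 15 pairs of groups. Replicate differences correlated at 0.035, 0.092 and, between both labels, 0.392 within day 1. Within day 3 they gave -0.072, -0.073 and 0.051. Only 0.392 was over 0.1, and no pairing was used.

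Lists of genes, 29 in number, were fixed before the data were examined, as were the groups, the contrasts, the rule for named genes and most alternatives. Of these lists 22 are of pathways or programmes and 7 of markers of other cells in the spleen. Each is named where its result is given, all 29 at day 1. A gene was represented by its probe set of highest mean over the 12 arrays. Genes without a probe set of their own were not measured, among them Suv39h1 and 9 of the 14 immunoglobulin genes. Lists were tested with camera at a preset correlation of 0.01 between genes and adjusted over the 29 lists of a contrast. Beside it stand camera with an estimated correlation and fry, whose PValue tests whether a list's genes move, on balance, one way and whose PValue.Mixed tests whether they change in either direction. Members not counted as risen or fallen did not pass. Statements on a list rest on the camera test, and numbers of members without 1 array are given for the comparisons with control. Named genes were Kdm4a, Kdm4c and 16 measured genes of the question in every contrast, the 8 largest rises and falls among probe sets of 1 gene that passed, did not overlap between groups and lay above the median level in the higher group, and the members of smallest p of each list that passed or had at least 3 members past the test. Of up to 4 such members per list the text names at most 3. For length, some genes that the rule selects are not named, among them Birc3, Dnajb9, Mxd4, Hdac2, Atf4 and Edem1, and some lists name none.

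Alternatives were quantile normalization, centring of arrays on their medians, leaving out dim probe sets, a prior variance without the trend, array weights, one probe set per gene, an adjusted p under 0.10, a floor of 1.5-fold, replicate number as a block, only the arrays of the same day, an estimated correlation, and leaving out each array in turn. An alternative set of pseudocounts was not run, since the values are log2. Leaving out day 3 control replicate 2 from contrasts not using it, and setting arrays labelled depleted against other-day controls, were chosen after seeing the data. The method was tested on data of simulated spread with 200 changed probe sets. Its rates need not hold for dim probe sets or the wide spread of day 3 controls. It recovered 53.5% of 1.5-fold, 96% of 2-fold and 100% of 4-fold changes in a day 1 comparison, and 26%, 74.5% and 100% in the change between days, with 8 to 17 false calls among 45037 probe sets. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.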

Results

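Gene expression was measured in mouse splenic B cells that carried the MD4 transgene, whose B cell receptor binds hen egg lysozyme (HEL). B220-positive cells were selected with magnetic beads and cultured with HEL, an antibody against CD40 and interleukin-21. The last 2 stand in for signals of follicular helper T cells, and HEL is the antigen of the receptor. Jmjd2a (Kdm4a) or Jmjd2c (Kdm4c), demethylases of histone H3 lysine 9, had been targeted by RNA interference, and the controls had received a non-targeting construct. The series was made to find genes that these demethylases regulate while B cells differentiate to plasma cells. Cells were collected at day 1 and day 3, with 2 arrays for each of the 6 groups. The titles call the replicates biological but name no separate cultures or animals. The p-values thus measure only the pooled spread within groups. The deposited log2 values had array medians between 5.2 and 5.26.

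The arrays labelled depleted at day 3 correlated more with the day 1 than with the day 3 controls. The first principal component held 43.8% of the variance, the second 27.5% and the third 8.6%. Across probe sets, which are not independent replicates, the day 1 control arrays correlated with the arrays labelled Jmjd2a-depleted and Jmjd2c-depleted at day 3 at a mean r of 0.9967 and 0.9954. Their mean r with the arrays labelled depleted at day 1 was 0.9897 and 0.9878, and with the day 3 controls it was 0.9809. Those labelled depleted at day 3 had a mean r of 0.9849 and 0.9876 with the day 3 controls. Arrays of the Jmjd2a and Jmjd2c labels correlated at 0.9966 at day 1 and 0.9964 at day 3, close to the 0.9959 to 0.9978 between replicates outside the day 3 control group. Day 3 control replicate 2 stood apart. Its interquartile range was 3.09, against 3.38 to 3.63 on the other arrays, and its r with replicate 1 was 0.9887. Its hybridisation controls read 11.341, against 10.297 to 10.832 elsewhere, and its 18S ribosomal RNA probe sets read 10.732, against 11.729 to 12.733. The replicate SD over all probe sets was 0.259 in day 3 controls, against 0.115 to 0.157 elsewhere. One model was fitted, so every comparison carries this spread.

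**Figure D1:**
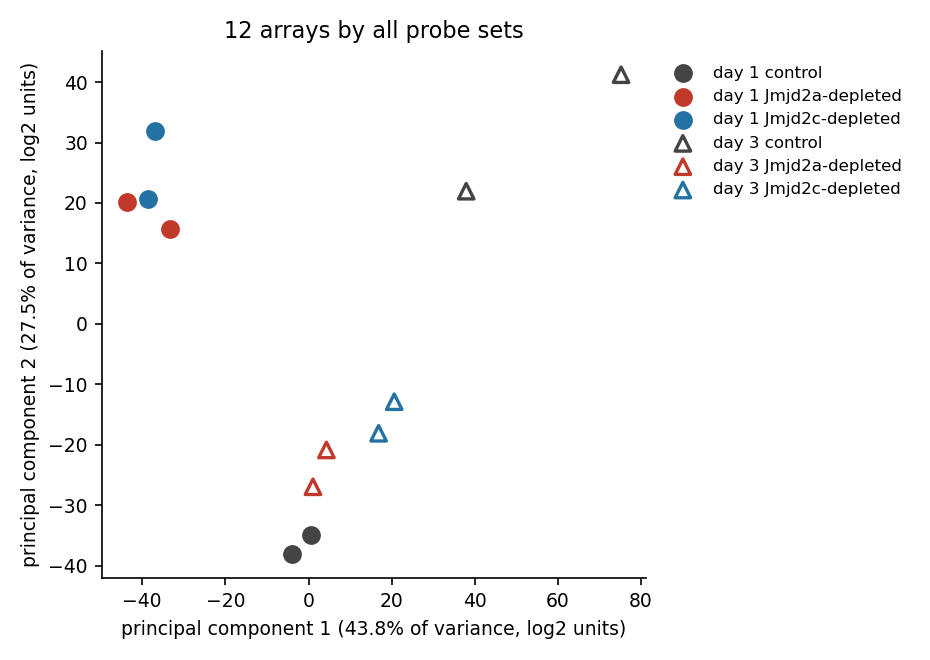
Principal components 1 (x axis, 43.8% of the variance) and 2 (y axis, 27.5%) of the 12 arrays, computed from all 45037 probe sets, with 1 point per array, colour for the treatment and shape for the day. The Jmjd2a arrays of day 3 sit beside the day 1 controls and the Jmjd2c arrays of day 3 between these and day 3 control replicate 1, while the day 3 controls and the arrays labelled depleted at day 1 lie apart from them in different directions.

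The targeted transcripts were not lower, past the test, on the arrays labelled for their depletion. Kdm4a by its brightest probe set was at 8.02 ± 0.11 (log2, mean ± SD of 2 arrays) on the Jmjd2a arrays of day 1 and at 7.91 ± 0.02 in their controls, a difference of 0.11 (95% interval -0.09 to 0.3, limma adjusted p = 0.62). At day 3 it was 8.06 ± 0.03 against 8.18 ± 0.02, a difference of -0.12 (-0.31 to 0.07, adjusted p = 0.36). With quantile normalization the day 3 difference was -0.287 at an adjusted p = 0.05, which did not pass. Kdm4c by its brightest probe set differed by 0.19 (-0.06 to 0.45, adjusted p = 0.41) on the Jmjd2c arrays of day 1, at 8 ± 0.03 against 7.81 ± 0.04. At day 3 it differed by 0.03 (-0.23 to 0.29, adjusted p = 0.91), at 7.79 ± 0.02 against 7.76 ± 0.29. That difference was -0.066 with quantile normalization and -0.17 without control replicate 2. The lowest levels inside the 95% intervals were 94.2% and 80.5% of control for Kdm4a at day 1 and day 3, and 95.7% and 85.5% for Kdm4c. The gene not targeted did not pass either: Kdm4a read 0.18 and -0.22 against control on the Jmjd2c arrays of day 1 and day 3, and Kdm4c 0.24 and 0.14 on the Jmjd2a arrays (adjusted p = 0.14 to 0.42). A second, dim Kdm4a probe set passed in none of these comparisons. As the transcripts do not bear out the labels, groups are called by label, and directions below are those of arrays so labelled.

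**Figure D2:**
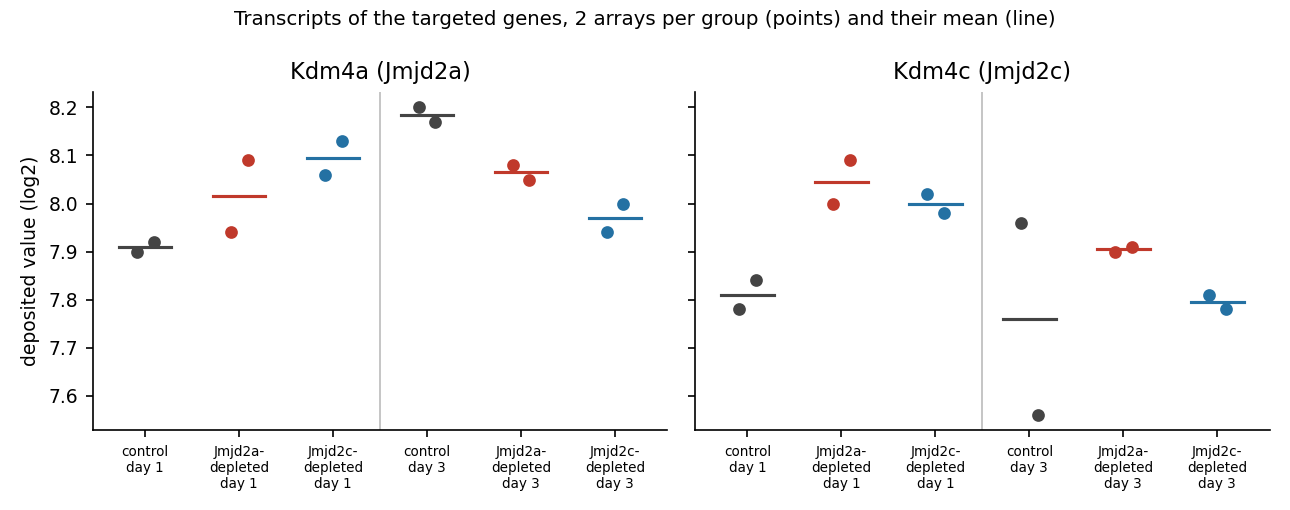
Log2 level (y axis) of Kdm4a and Kdm4c on each of the 12 arrays by group (x axis), where points are arrays and lines are means of 2. The Kdm4a means span 7.91 to 8.18 and the Kdm4c means 7.76 to 8.05, and neither targeted group lies below its same-day control past the test.

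At day 1 the arrays labelled depleted showed large rises, many of them in genes of resting B cells, macrophages and the immediate early response, and small falls spread over genes of dividing cells. Values are given for the Jmjd2a and then for the Jmjd2c label, as log2 differences from control, and a single value holds for both. Medians are over the members of a list, counts in the list alone adjust p-values over that list only, adjusted p-values of lists are those of camera, and arrays are named by group and replicate number. The largest rises, each ± SE, were Vcam1 (6.46 ± 0.25 and 6.82 ± 0.25), a stromal and macrophage adhesion molecule, and Fos (5.35 ± 0.16 and 5.65 ± 0.16), an immediate early factor. Then came C1qb (5.14 ± 0.45 and 5.64 ± 0.32, by 2 probe sets), a macrophage complement chain. They were followed by Ltb (4.99 and 5.29), which encodes lymphotoxin beta, Fcer2a (4.96 and 5.29), the low-affinity IgE receptor CD23 of mature B cells, Hspa1b (4.67 and 4.73), a heat-shock protein, Slc40a1 (4.64 and 4.85), the iron exporter ferroportin, and Csf1r (4.43 and 4.84), the macrophage growth factor receptor (SE 0.16 to 0.53, limma adjusted p = 2.4e-09 to 0.00025). The largest falls shared by the top of both rankings were Kif11 (-1.32 ± 0.15 and -1.38 ± 0.15), a mitotic kinesin, Smc1a (-0.96 ± 0.11 and -1.19 ± 0.11), a cohesin subunit, Cldnd1 (-1.02 and -1.18), Gsdme (-1.01 and -1.13), and Srsf11 (-0.92 and -1.21). With the Jmjd2a label Phip (-1.04), Hells (-1), and Eml4 (-0.94) completed the largest falls, and with the Jmjd2c label Pnn (-1.11), Eprs (-1.08), and Seh1l (-1.07) (adjusted p up to 0.011). By limma with Benjamini-Hochberg adjustment, 3366 and 4961 of 45037 probe sets changed, 1904 and 2397 higher and 1462 and 2564 lower. At least 2-fold, 617 and 744 were higher and 6 and 18 lower. Without control replicate 1 the counts were 1162 and 1829, without control replicate 2 they were 1043 and 1900, without Jmjd2a replicate 1 the first was 1402, and without Jmjd2c replicate 1 or 2 the second was 3296 or 2450. In the fit without day 3 control replicate 2 they were 6704 and 8449, and with array weights 6378 and 8386. Without 1 array these gene calls ended or moved by over 1.5 times, with the Jmjd2a label Srsf11 (-0.87 without control 1) and Phip (-1.11 to -0.79 without control 1 or 2 or Jmjd2a 2). With the Jmjd2c label they were Eprs (-0.74 and -1.01 without control 1 or Jmjd2c 2).

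Genes of mature B cells and of antigen presentation rose together at day 1. Of the mature B cell identity list, 17 and 19 of 23 rose with no fall (20 up and 0 and 1 down in the list alone). The median was 0.64 and 0.79 (adjusted p = 8.7e-21 and 7.6e-19). Fcer2a (4.96 and 5.29) and Cr2 (3.92 and 4.04), the complement receptor CD21, led it, with Ms4a1 (1.79 and 1.9), which encodes CD20. In MHC class II presentation, 10 of 10 rose with no fall (10 in the list alone), among them H2-Ob (2.42 and 2.6) and H2-Aa (0.37 and 0.42). The median was 0.95 and 1.12 (adjusted p = 5e-18 and 3.1e-17). Immediate early and stress genes respond within minutes to stimulation or handling. Of these, 12 and 13 of 23 rose and 1 and 3 fell (14 and 16 up and 2 and 4 down in the list alone), led by Fos (5.35 and 5.65) and Klf4 (3.21 and 3.38). The median was 0.55 and 0.61 (adjusted p = 4.8e-12 and 3.1e-10, but 0.044 and 0.058 with an estimated correlation). Of cyclin-dependent kinase inhibitors and quiescence genes, 8 and 9 of 20 rose and 1 fell (11 and 10 up and 3 and 2 down in the list alone). The median was 0.32 and 0.22 (adjusted p = 5.7e-06 and 0.0017, but 0.1 and 0.23 with an estimated correlation). Btg1 (0.82 and 0.78) and Klf2 (3.71 and 4), markers of resting lymphocytes, rose most surely. In the plasma cell programme 8 of 21 rose and 1 fell (11 and 12 up and 1 down in the list alone), with Mzb1 (0.57 and 0.68) up. The median was 0.31 and 0.35 (adjusted p = 2.4e-07 and 3.2e-05, but 0.1 and 0.19 with an estimated correlation). Of the immunoglobulin genes 2 and 3 of 5 rose with no fall (4 in the list alone), with Ighm (0.36 and 0.39) up. The median was 0.36 and 0.39 (adjusted p = 2e-04 and 0.00049, but 0.1 and 0.14 with an estimated correlation). All these moved while on the same arrays macrophage markers had a median of 1.9 and 1.91. The 18S probe sets of these arrays read 11.729 to 12.537, against 12.685 and 12.733 in the controls, and 3' minus 5' Actb probe sets differed by 0.415 to 0.544, against 0.41 and 0.428. The fallen members with Jmjd2c numbered 0 to 1 for immediate early genes without control 1 or 2 or Jmjd2c 1. In number, risen members with Jmjd2a came to 4 to 5 for kinase inhibitors and 3 to 5 for plasma cell genes without control 1 or 2 or Jmjd2a 1. Counts of risen members with Jmjd2c were 3 to 4 for plasma cell genes without control 1 or 2 or Jmjd2c 2.

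Among the genes followed in every comparison, Irf4 (0.49 and 0.48), Jchain (0.97 and 1.07) and Cdkn1b (0.75 and 0.79) rose and Sdc1 (-0.41 and -0.51), Ccnd2 (-0.32 and -0.36), Cdkn3 (-0.4 and -0.38) and Mki67 (-0.21 and -0.31) fell (largest adjusted p = 0.047). Irf4 is a transcription factor and Jchain and Sdc1 (CD138) are products of plasma cells, Cdkn1b and Cdkn3 act on cell-cycle kinases, Ccnd2 is a D cyclin and Mki67 marks dividing cells. Myc (0.27 and 0.4) rose past the test with the Jmjd2c label (adjusted p = 0.021) and not with the Jmjd2a label (adjusted p = 0.14), and no probe set differed between the labels. Values that did not pass were Prdm1 (-0.04 and -0.25), Xbp1 (0.12 and 0.11), Pax5 (0.01 and -0.09), Bcl6 (0.23 and 0.18), Bach2 (-0.1 and -0.13), Wdr5 (-0.11 and -0.16), Cdkn2c (-0.35 and -0.28) and Nfkbia (-0.08 and -0.04), with adjusted p = 0.15 to 0.99. Gene calls that ended or moved by over 1.5 times without 1 array were, with the Jmjd2a label Irf4 (0.35 to 0.51 without control 1 or 2 or Jmjd2a 2), Cdkn1b (0.57 to 0.79 without control 1 or 2 or Jmjd2a 1), Sdc1 (-0.46 to -0.27 without control 1 or 2 or Jmjd2a 1), Ccnd2 (-0.30 without control 1), Cdkn3 (-0.47 to -0.34 without control 1 or 2 or Jmjd2a 1 or 2) and Mki67 (-0.23 to -0.20 without control 1 or 2 or Jmjd2a 1 or 2). With the Jmjd2c label they were Irf4 (0.39 to 0.51 without control 1 or 2 or Jmjd2c 2), Cdkn1b (0.76 without control 1), Sdc1 (-0.46 without control 2), Cdkn3 (-0.41 to -0.36 without control 1 or 2 or Jmjd2c 1 or 2), Mki67 (-0.29 without control 1) and Myc (0.25 to 0.43 without control 1 or 2 or Jmjd2c 2).

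Genes of dividing cells fell at day 1, by less than the largest rises. Of the mitosis (G2/M) list, 21 and 22 of 29 fell with no rise (27 in the list alone), with Bub1 (-0.54 and -0.59) and Kif20a (-0.7 and -0.66), a spindle checkpoint kinase and a kinesin. The median was -0.41 and -0.42 (adjusted p = 6.8e-16 and 1.2e-15). Of the DNA replication (G1/S) list, 22 and 25 of 30 fell with no rise (29 in the list alone), with Rrm2 (-0.39 and -0.41) and Mcm5 (-0.34 and -0.36), a ribonucleotide reductase subunit and a replicative helicase subunit. The median was -0.37 and -0.39 (adjusted p = 5e-18 and 9.1e-17). Of Myc targets and ribosome biogenesis genes, 19 and 23 of 27 fell with no rise (25 and 26 in the list alone), among them Hspd1 (-0.24 and -0.25), a mitochondrial chaperone. The median was -0.26 and -0.27 (adjusted p = 3.6e-15 and 2.4e-15). In cholesterol synthesis 13 of 16 fell with no rise (15 in the list alone), with Hmgcs1 (-0.28 and -0.39) and Fdft1 (-0.39 and -0.48). The median was -0.34 and -0.39 (adjusted p = 2.1e-11 and 7.2e-12). In glycolysis 0 and 1 of 15 rose and 8 fell (1 up and 8 down in the list alone), with Pgam1 (-0.29 and -0.3). The median was -0.24 and -0.19 (adjusted p = 1.6e-05 and 0.00014). These 5 lists passed with an estimated correlation as well (largest adjusted p = 0.028). Of the germinal centre programme, 0 and 1 of 14 rose and 3 and 4 fell (0 and 2 up and 3 and 5 down in the list alone), and Ung (-0.58 and -0.52), a uracil glycosylase, fell. The median was -0.2 (adjusted p = 0.12 and 0.15). Of the IL-21 and STAT3 signalling genes, 0 and 1 of 16 rose and 4 fell (1 up and 6 down in the list alone), including Il21r (-0.42 and -0.37), the interleukin-21 receptor. The median was -0.23 and -0.19 (adjusted p = 0.012 and 0.065, but 0.1 and 0.21 with an estimated correlation). Beside these falls, on the same arrays macrophage markers had a median of 1.9 and 1.91. Leaving out 1 array ended or moved, by over 1.5 times, with the Jmjd2a label Hspd1 (-0.21 without control 2). Among lists, germinal centre genes with Jmjd2a (adjusted p = 0.022 without Jmjd2a 2) gained a call. Members fallen with Jmjd2a numbered 6 to 8 for mitosis, 6 to 11 for DNA replication, 2 to 5 for Myc targets, 4 to 6 for cholesterol synthesis and 1 for IL-21 and STAT3 without control 1 or 2 or Jmjd2a 1 and 2 to 4 for glycolysis without control 1 or 2. Fallen members with Jmjd2c numbered 9 to 13 for mitosis, 8 to 15 for DNA replication, 10 to 12 for Myc targets and 6 to 8 for cholesterol synthesis without control 1 or 2 or Jmjd2c 2 and 5 for glycolysis without control 2 or Jmjd2c 2.

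Markers of other spleen cells rose with the B cell genes at day 1. Of the macrophage and monocyte markers, 13 and 14 of 18 rose with no fall (15 and 14 in the list alone), with Vcam1 (6.46 and 6.82) and Csf1r (4.43 and 4.84). The median was 1.9 and 1.91 (adjusted p = 5.6e-17 and 2.4e-15, but 0.044 and 0.058 with an estimated correlation). Of the NK cell markers, 7 and 8 of 9 rose with no fall (8 and 9 in the list alone), with Klra8 (2.11 and 2.15) and Gzma (2.81 and 3.16). The median was 0.88 and 1.06 (adjusted p = 1.3e-10 and 5.3e-11). Of the T cell markers, 4 and 5 of 13 rose with no fall (6 and 7 in the list alone), with Cd2 (1.49 and 1.81). The median was 0.26 and 0.44 (adjusted p = 0.00028 and 2e-04). Of the erythroid and platelet markers, 2 and 4 of 11 rose with no fall (2 and 5 in the list alone), with Slc4a1 (3.91 and 4.11), the red cell anion exchanger. The median was 0.16 and 0.45 (adjusted p = 0.00074 and 2e-04). Neutrophil markers passed as a list although 0 of 10 rose or fell (0 and 2 up and 0 down in the list alone). The median was 0.97 and 1.49 (adjusted p = 0.0045 and 0.00064, but 0.31 and 0.23 with an estimated correlation). Of dendritic cell markers 1 and 3 of 10 rose with no fall (1 and 3 in the list alone). The median was 0.03 and 0.06 (adjusted p = 0.12 and 0.055). Of stromal markers 0 of 8 rose or fell (0 in the list alone). The median was -0.06 and -0.01 (adjusted p = 0.84 and 0.6). Replicate 2 of both labels stood higher than replicate 1 in the mean log2 level of neutrophil markers (6.691 and 7.298 against 4.969 and 4.994), macrophage markers (7.779 and 8.236 against 7.413 and 7.312) and immunoglobulin genes (12.444 and 12.611 against 11.78 and 11.796). Of the list calls, neutrophil markers with Jmjd2a (adjusted p = 0.22 without Jmjd2a 2) and neutrophil markers with Jmjd2c (adjusted p = 0.081 without Jmjd2c 2) lost the call, and dendritic cell markers with Jmjd2c (adjusted p = 0.034 without control 1) gained a call. The risen members with Jmjd2a numbered 8 for macrophage markers without control 2, 1 for T cell markers without control 1 or 2 or Jmjd2a 1 and 4 for erythroid markers without Jmjd2a 2. In number, risen members with Jmjd2c came to 1 to 3 for T cell markers without control 1 or 2 or Jmjd2c 1 or 2, 2 for erythroid markers without control 1 or 2 and 7 for neutrophil markers without Jmjd2c 1.

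Chromatin and signalling lists moved little at day 1. Of the JmjC and LSD demethylases, 5 and 6 of 21 rose and 2 fell (7 and 8 up and 3 down in the list alone), with Kdm7a (1.39 and 1.5), an H3 lysine 9 and 27 demethylase, up. The median was 0.11 and 0.1 (adjusted p = 0.021 and 0.065, but 0.3 and 0.41 with an estimated correlation). No call was made for the following lists. In the H3K9 methylation and heterochromatin list 1 and 2 of 16 rose and 2 and 3 fell (3 up and 8 down in the list alone). The median was -0.21 and -0.19 (adjusted p = 0.19 and 0.17). In the H3K4 methyltransferase (COMPASS) complexes 3 and 2 of 15 rose and 0 and 1 fell (3 and 2 up and 1 down in the list alone). The median was 0.04 and 0.05 (adjusted p = 0.18 and 0.34). In NF-kB pathway and targets 5 and 8 of 33 rose and 3 and 5 fell (7 and 9 up and 7 down in the list alone). The median was 0.02 and 0.08 (adjusted p = 0.18 and 0.13). In the type I interferon response 3 of 28 rose and 1 and 2 fell (4 and 5 up and 2 down in the list alone). The median was 0.02 and 0.04 (adjusted p = 0.095 and 0.23). In p53 targets and apoptosis 2 of 20 rose and 1 and 2 fell (2 and 3 up and 3 down in the list alone). The median was -0.01 and -0.09 (adjusted p = 0.39 and 0.94). In the secretory pathway and unfolded protein response 4 and 3 of 30 rose and 1 and 4 fell (4 and 5 up and 2 and 9 down in the list alone). The median was -0.02 and -0.06 (adjusted p = 0.74 and 0.3). In G1 cyclins and Myc 2 and 5 of 11 rose and 2 and 3 fell (5 up and 2 and 3 down in the list alone). The median was -0.02 and 0.1 (adjusted p = 0.34 and 0.2). Among reference genes 1 of 10 rose and 3 fell (1 up and 3 down in the list alone). The median was -0.08 and -0.11 (adjusted p = 0.079 and 0.14). Median, mean and test differed in sign for the secretory, G1 cyclin and p53 lists with the Jmjd2a label and for the p53 and stromal lists with the Jmjd2c label. The interferon median turned from 0.02 to -0.01 with quantile normalization for the Jmjd2a label. At the level of lists, demethylases with Jmjd2a (adjusted p = 0.065 and 0.1 without control 2 or Jmjd2a 1) lost the call, and demethylases with Jmjd2c (adjusted p = 0.034 without control 1) and reference genes with Jmjd2a (adjusted p = 0.011 without Jmjd2a 1) gained a call. Counts of risen members with Jmjd2a were 2 for demethylases without control 1 or 2 or Jmjd2a 1.

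**Figure D3:**
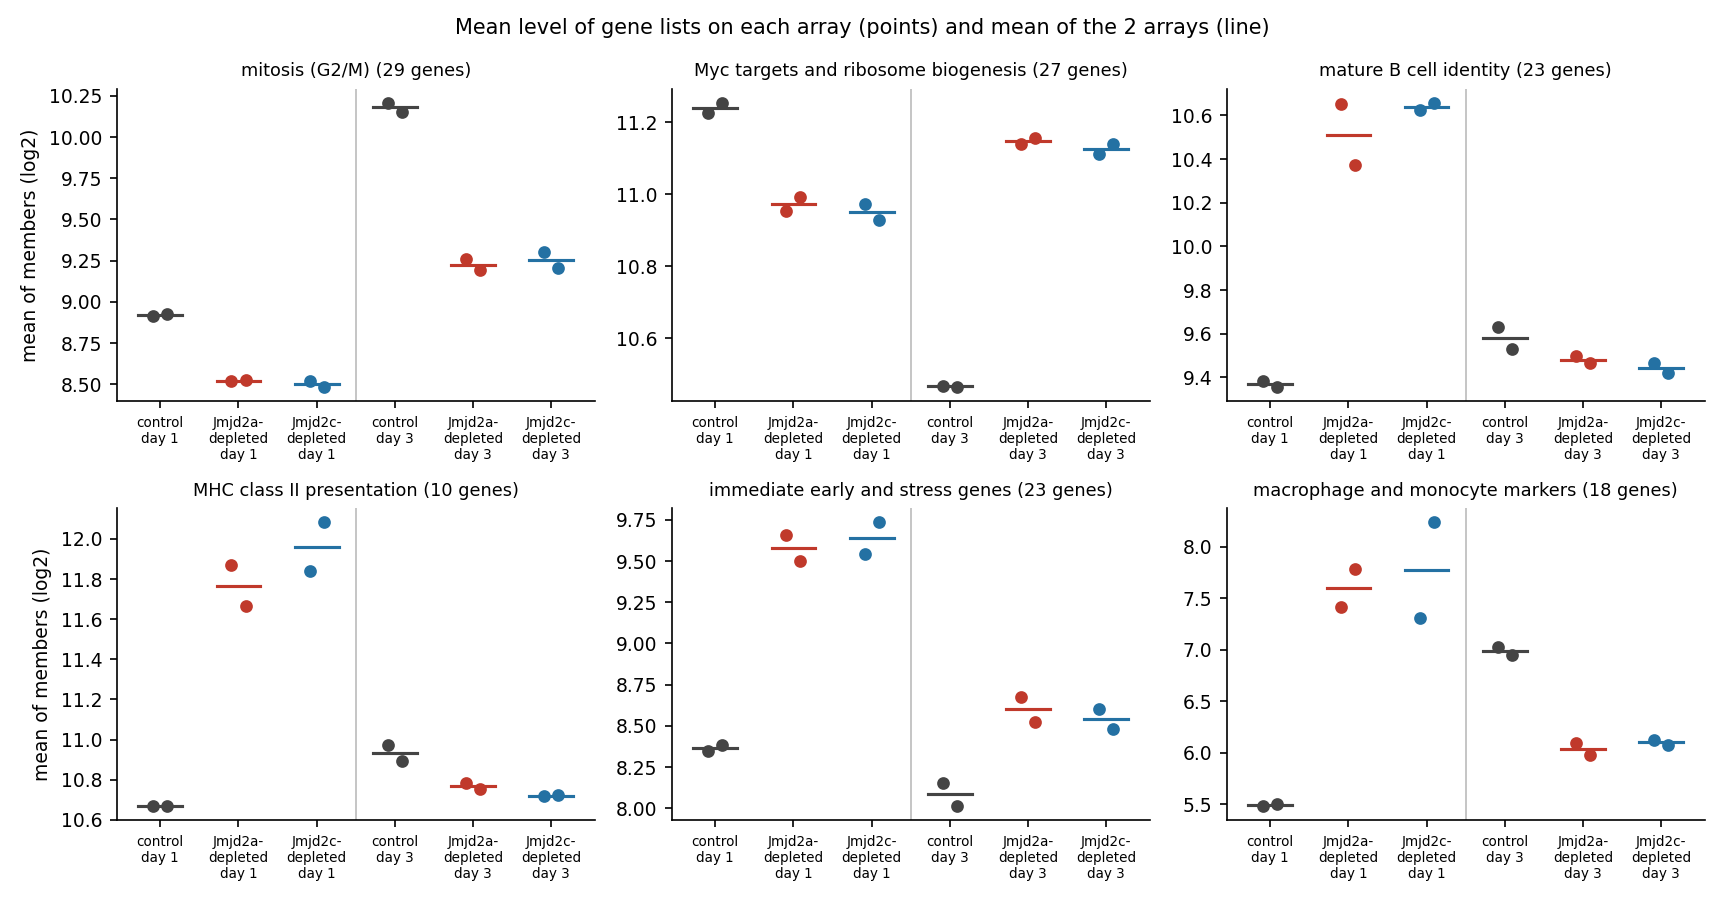
Mean log2 level (y axis) of 6 gene lists on each array, by group (x axis), where points are arrays and lines are means of 2. Mature B cell, MHC class II, immediate early and macrophage genes are highest on the arrays labelled depleted at day 1, and mitosis genes are highest and Myc and ribosome biogenesis genes lowest in the day 3 controls.

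At day 3 the arrays labelled depleted had lower levels of mitotic genes and higher levels of Myc target and ribosome biogenesis genes than the controls. The largest rises were Pcp4 (4.22 ± 0.18 and 4.14 ± 0.18), a calmodulin-binding peptide, Hspa1b (3.37 ± 0.51 and 3.1 ± 0.51), Rgs13 (3.18 ± 0.18 and 3.08 ± 0.18), a regulator of G protein signalling in germinal centre B cells, and Pigr (2.9 and 2.84), the polymeric immunoglobulin receptor. Maf (2.9 and 2.61), a transcription factor, Serpinb1a (2.81 and 2.83), a protease inhibitor, Kdm6b (2.65 and 2.55), an H3 lysine 27 demethylase, and Xrcc5 (2.54 and 2.48), a subunit of the DNA end-binding factor Ku, completed them (limma adjusted p = 3.2e-07 to 0.0013). The rankings are by probe set: by its brightest, used in lists, Kdm6b was 1.04 and 0.97. Across probe sets, day 3 differences correlated with the control change from day 1 at r = -0.929 and -0.896, against -0.5 in unchanged simulated groups. Of the largest falls, Gzma (-2.33 ± 0.27 and -2.29 ± 0.27), Fabp4 (-2.32 ± 0.21 and -2.51 ± 0.21) and Fnbp1l (-2.18 ± 0.14 and -2.06 ± 0.14), a granzyme, a fatty acid binding protein and an actin regulator, were shared by both rankings, as were 2900026A02Rik (-2.39 and -2.23), Gpr34 (-2.17 and -2.54) and S100a4 (-2.14 and -2.19). Cdkn2a (-2.27), a cell-cycle inhibitor, and Gzmb (-2.12), a granzyme induced by interleukin-21 in B cells, completed those of the Jmjd2a label, and C1qb (-2.11) and the chemokine Ccl22 (-2) those of the Jmjd2c label. In limma, after Benjamini-Hochberg adjustment, 9351 and 6452 probe sets changed, 6149 and 4181 higher and 3202 and 2271 lower, and 613 and 307 were at least 2-fold higher and 315 and 324 at least 2-fold lower. Without control replicate 1, which leaves the control replicate of low quality alone, the counts were 17389 and 12578, and without control replicate 2 they were 7759 and 7223. Without Jmjd2a replicate 1 or 2 the first was 5434 or 4240, and without Jmjd2c replicate 1 or 2 the second was 3654 or 2941. With array weights they were 5711 and 4114. Without 1 array these gene calls ended or moved by over 1.5 times, with the Jmjd2c label C1qb (-1.71 without Jmjd2c 2).

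Cell-cycle lists split at day 3. Of the mitosis (G2/M) list, 29 of 29 fell with no rise (29 in the list alone), with Ccnb2 (-1.54 and -1.48) and Ube2c (-1.38 and -1.31), a mitotic cyclin and the ubiquitin carrier of the anaphase-promoting complex. The median was -0.96 (adjusted p = 1.5e-25 and 1.2e-30). Of Myc targets and ribosome biogenesis genes, 27 of 27 rose with no fall (27 in the list alone), with Srm (1.08 and 1.1) and Odc1 (0.75 and 0.72), enzymes of polyamine synthesis. The median was 0.67 and 0.65 (adjusted p = 1.7e-25 and 4.2e-28). Both lists passed with an estimated correlation (largest adjusted p = 0.038). In the DNA replication (G1/S) list 18 of 30 rose and 3 fell (19 up and 3 down in the list alone), with Cdt1 (0.91 and 0.93) and Mcm4 (0.56 and 0.47), which load and form the replicative helicase. The median was 0.34 and 0.29 (adjusted p = 1.8e-07 and 1.1e-06, but 0.16 and 0.21 with an estimated correlation). Of G1 cyclins and Myc, 5 of 11 rose and 1 fell (6 and 5 up and 2 and 1 down in the list alone): Myc (1.28 and 1.08) and Ccnd2 (0.87 and 0.84) rose. The median was 0.45 and 0.34 (adjusted p = 0.031 and 0.016, but 0.33 and 0.27 with an estimated correlation). In glycolysis 8 and 6 of 15 rose with no fall (8 in the list alone), with Slc16a1 (1.38 and 1.24) and Hk2 (0.93 and 0.91), a lactate transporter and a hexokinase. The median was 0.26 and 0.19 (adjusted p = 4e-04 and 0.00025, but 0.1 and 0.095 with an estimated correlation). In cholesterol synthesis 10 and 9 of 16 rose and 0 and 1 fell (11 and 9 up and 1 down in the list alone), with Cyp51 (0.69 and 0.66) and Idi1 (0.47 and 0.41). The median was 0.34 and 0.27 (adjusted p = 4e-05 and 0.00025, but 0.16 and 0.21 with an estimated correlation). Of the cyclin-dependent kinase inhibitors and quiescence genes, 3 and 1 of 20 rose and 8 and 11 fell (4 and 2 up and 12 down in the list alone), including Cdkn3 (-1.47 and -1.51), Cdkn1b (-0.66 and -0.69) and Cdkn2c (-0.44 and -0.49), and Mki67 (-0.96 and -0.97) fell as well. The median was -0.3 and -0.32 (adjusted p = 0.0026 and 0.00027, but 0.29 and 0.27 with an estimated correlation). Of p53 targets and apoptosis genes, 1 of 20 rose and 9 and 8 fell (2 and 1 up and 9 and 10 down in the list alone), with Bcl2l11 (-1.55 and -1.4) and Ccng1 (-0.7 and -0.69), the pro-apoptotic protein Bim and a p53-induced cyclin, down. The median was -0.31 and -0.36 (adjusted p = 0.0037 and 0.00017, but 0.16 and 0.11 with an estimated correlation). The members named passed at an adjusted p of at most 0.039. Beside all of these, the day 3 controls held replicate 2, whose 18S probe sets read 10.732 and whose interquartile range was 3.09. Gene calls that ended or moved by over 1.5 times without 1 array were, with the Jmjd2a label Cdkn1b (-0.41 and -0.62 without control 1 or Jmjd2a 1) and Cdkn2c (-0.67 to -0.21 without control 1 or 2 or Jmjd2a 1 or 2). With the Jmjd2c label they were Cdkn1b (-0.73 to -0.43 without control 1 or Jmjd2c 1 or 2) and Cdkn2c (-0.50 to -0.26 without control 1 or Jmjd2c 1 or 2). Among lists, G1 cyclins and Myc with Jmjd2a (adjusted p = 0.064 without control 2) and G1 cyclins and Myc with Jmjd2c (adjusted p = 0.071 without control 2) lost the call. Members fallen with Jmjd2a numbered 1 for DNA replication without Jmjd2a 1 or 2 and 5 for kinase inhibitors without Jmjd2a 1. Fallen members with Jmjd2c numbered 1 for DNA replication and 4 for kinase inhibitors without Jmjd2c 1 or 2 and 5 for p53 targets without Jmjd2c 2. The risen members with Jmjd2a numbered 5 for glycolysis without Jmjd2a 1 or 2, 1 for kinase inhibitors without control 2 or Jmjd2a 1 or 2 and 3 for p53 targets without control 1. In number, risen members with Jmjd2c came to 4 for kinase inhibitors without control 1.

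By camera at its preset correlation alone, the plasma cell list was lower and the germinal centre list higher at day 3 on the arrays labelled depleted. Of the plasma cell list, 2 of 21 rose and 11 fell (3 and 2 up and 12 down in the list alone). The median was -0.34 and -0.35 (adjusted p = 0.011 and 0.00025, but 0.36 and 0.27 with an estimated correlation). Xbp1 (-0.68 and -0.65) and Mzb1 (-0.84 and -0.8), the transcription factor of the secretory programme and a chaperone of immunoglobulin assembly, fell, and Sdc1 (1.11 and 1.07) rose. Of the immunoglobulin genes, 3 of 5 fell with no rise (4 in the list alone), with Jchain (-0.84 and -0.83) and Ighm (-0.38 and -0.36) down, although another probe set of Ighm passed in the opposite direction. The median was -0.52 and -0.36 (adjusted p = 0.005 and 0.0041, but 0.27 with an estimated correlation). Of the germinal centre programme, 8 and 6 of 14 rose and 2 fell (8 up and 2 down in the list alone), with Rgs13 (3.18 and 3.08), Ung (1.29 and 1.26) and Bcl6 (0.51 and 0.46), the last a germinal centre repressor. The median was 0.43 and 0.38 (adjusted p = 0.0096 and 0.014, but 0.33 and 0.34 with an estimated correlation). In the secretory pathway and unfolded protein response 11 of 30 rose and 2 and 3 fell (14 and 12 up and 3 down in the list alone). The median was 0.13 and 0.07 (adjusted p = 0.036 and 0.066, but 0.36 and 0.48 with an estimated correlation). In mature B cell identity 4 of 23 rose and 9 fell (5 and 4 up and 11 and 13 down in the list alone), with Id3 (1.15 and 1.09) and Bach2 (0.61 and 0.48) up and Cd72 (-0.71 and -0.63) down. The median was -0.23 and -0.24 (adjusted p = 0.079 and 0.016, but 0.51 and 0.46 with an estimated correlation). Prdm1, which encodes the plasma cell repressor Blimp-1, did not pass, nor did the transcription factors Irf4 and Pax5 or the NF-kB inhibitor Nfkbia, with values of Prdm1 (0.05 and -0.17), Irf4 (-0.1 and -0.21), Pax5 (0.07 and 0) and Nfkbia (0.03 and 0.09) and adjusted p = 0.11 to 1. Another probe set of Pax5 passed with the opposite sign for the Jmjd2a label. On the same arrays macrophage markers had a median of -1.11 and -1.01 and NK cell markers of -1.29 and -1.25, and the controls included replicate 2, with its interquartile range of 3.09. Leaving out 1 array ended or moved, by over 1.5 times, with the Jmjd2c label Bcl6 (0.45 without Jmjd2c 2). Of the list calls, plasma cell genes with Jmjd2a (adjusted p = 0.091 without control 1), germinal centre genes with Jmjd2c (adjusted p = 0.092 without control 2), the secretory pathway with Jmjd2a (adjusted p = 0.05 to 0.09 without control 1 or 2 or Jmjd2a 2) and mature B cell genes with Jmjd2c (adjusted p = 0.091 without control 1) lost the call. Counts of risen members with Jmjd2a were 4 for plasma cell genes without control 1, 5 for germinal centre genes without Jmjd2a 2 and 6 to 7 for the secretory pathway without Jmjd2a 1 or 2. Members fallen with Jmjd2a numbered 6 to 7 for plasma cell genes without Jmjd2a 1 or 2. Fallen members with Jmjd2c numbered 5 to 6 for plasma cell genes without Jmjd2c 1 or 2 and 4 for mature B cell genes without Jmjd2c 2. The risen members with Jmjd2c numbered 3 for germinal centre genes without Jmjd2c 2.

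Signalling lists at day 3 gave calls in both directions. In the IL-21 and STAT3 list 9 and 6 of 16 rose and 1 and 2 fell (10 and 7 up and 2 down in the list alone), with Gzmb (-2.12 and -1.98) down. The median was 0.25 and 0.24 (adjusted p = 0.011 and 0.035, but 0.16 and 0.27 with an estimated correlation). Of immediate early and stress genes 10 and 9 of 23 rose and 1 and 2 fell (12 and 11 up and 4 and 5 down in the list alone), with Egr2 (1.02 and 0.95) and Ier2 (1.13 and 1.15) up. The median was 0.31 and 0.19 (adjusted p = 0.017 and 0.029, but 0.36 and 0.48 with an estimated correlation). In the type I interferon response 7 and 5 of 28 rose and 8 and 9 fell (8 and 6 up and 10 and 12 down in the list alone), with Gbp2 (-1.63 and -1.71) and Gbp3 (-1.38 and -1.49), interferon-induced GTPases, down. The median was -0.18 and -0.2 (adjusted p = 0.24 and 0.026, but 0.63 and 0.49 with an estimated correlation). The NF-kB list did not pass, with Rel (1.24 and 1.2), an NF-kB subunit, up and Ebi3 (-1.43 and -1.35), a cytokine subunit, down. The controls compared here include replicate 2, with its interquartile range of 3.09. At the level of lists, IL-21 and STAT3 with Jmjd2c (adjusted p = 0.13 and 0.088 without control 2 or Jmjd2c 2), immediate early genes with Jmjd2a (adjusted p = 0.067 without control 2), immediate early genes with Jmjd2c (adjusted p = 0.05 and 0.16 without control 1 or 2) and interferon with Jmjd2c (adjusted p = 0.31 without control 1) lost the call, and interferon with Jmjd2a (adjusted p = 0.025 without control 2) gained a call. In number, risen members with Jmjd2a came to 4 to 5 for IL-21 and STAT3 without Jmjd2a 1 or 2. Counts of fallen members with Jmjd2a were 3 for IL-21 and STAT3 without control 2. Members risen with Jmjd2c numbered 2 to 3 for IL-21 and STAT3 without Jmjd2c 1 or 2, 3 for interferon without Jmjd2c 2 and 8 for interferon without control 1. Fallen members with Jmjd2c numbered 14 for interferon without control 2.

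Chromatin lists and markers of other cells were compared in the same way at day 3. Of the H3K4 methyltransferase (COMPASS) complexes, 6 and 5 of 15 rose with no fall (6 and 5 in the list alone), with Wdr5 (0.48 and 0.47), a core subunit, up. The median was 0.24 and 0.21 (adjusted p = 0.0013 and 0.017, but 0.36 and 0.49 with an estimated correlation). Of the JmjC and LSD demethylases, 5 and 3 of 21 rose and 0 and 1 fell (6 and 4 up and 0 and 1 down in the list alone), with Riox1 (0.72) up. The median was 0.14 and 0.01 (adjusted p = 0.054 and 0.42). Of the H3K9 methylation and heterochromatin list, 4 of 16 rose and 1 and 2 fell (6 and 4 up and 2 down in the list alone). The median was 0.03 and 0.06 (adjusted p = 0.29 and 0.36). Quantile normalization turned the sign of the median for the H3K9 list with the Jmjd2a label, from 0.03 to -0.06, and for the demethylases with the Jmjd2c label, from 0.01 to -0.06. Of the macrophage and monocyte markers, 12 and 10 of 18 fell with no rise (16 and 15 in the list alone), with Vcam1 (-1.79 and -1.68) and Mpeg1 (-0.97 and -0.96). The median was -1.11 and -1.01 (adjusted p = 3.6e-06 and 1.8e-06, but 0.27 with an estimated correlation). Of the NK cell markers, 6 of 9 fell with no rise (7 in the list alone), with Nkg7 (-1.4 and -1.25) and Gzma (-2.33 and -2.29). The median was -1.29 and -1.25 (adjusted p = 3.5e-05, but 0.16 and 0.19 with an estimated correlation). MHC class II genes, the other marker lists and the reference genes did not pass, with Flt3 (-1.5 and -1.64), a receptor of dendritic cell precursors, down. The erythroid median turned from -0.08 to 0.03 with quantile normalization for the Jmjd2a label. Among lists, H3K4 methyltransferases with Jmjd2c (adjusted p = 0.13 without control 2) lost the call, and demethylases with Jmjd2a (adjusted p = 0.045 and 0.034 without control 1 or Jmjd2a 1) gained a call. The risen members with Jmjd2c numbered 1 to 2 for H3K4 methyltransferases without Jmjd2c 1 or 2 and 8 for H3K4 methyltransferases without control 1. In number, fallen members with Jmjd2a came to 4 for macrophage markers without Jmjd2a 2. Counts of fallen members with Jmjd2c were 3 to 4 for macrophage markers without Jmjd2c 1 or 2.

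Both labels gave largely overlapping calls against their shared controls. At day 1, 1732 probe sets were higher and 1335 lower with both labels, 3067 in all, and 0 were called in opposite directions. Independent lists of the same sizes would share 101 and 83.2. At day 3, 4030 were higher and 1877 lower with both, 5907 in all, against 571 and 161, and 0 were opposite. Across probe sets, the log2 differences of the labels correlated at r = 0.933 at day 1 and 0.886 at day 3, where unchanged groups simulated against shared controls gave 0.5 and 0.501 and 0 shared calls. The covariance was 0.107 and 0.1063, against 0.0107 in both simulations. The controls cannot be split into parts of 2 arrays, so part of the excess can come from the shared controls, whose own spread was 0.0068 at day 1 and 0.0336 at day 3 as a covariance. The overlap of day 1 was 1082 or 1000 without control replicate 1 or 2, 1331 without Jmjd2a replicate 1 and 2014 without Jmjd2c replicate 2. That of day 3 was 11831 without control replicate 1, 3767 without Jmjd2a replicate 2, and 3540 or 2866 without Jmjd2c replicate 1 or 2. With array weights they were 5667 and 3878. At day 1 the replicate differences of both labels correlated at 0.392.

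**Figure D4:**
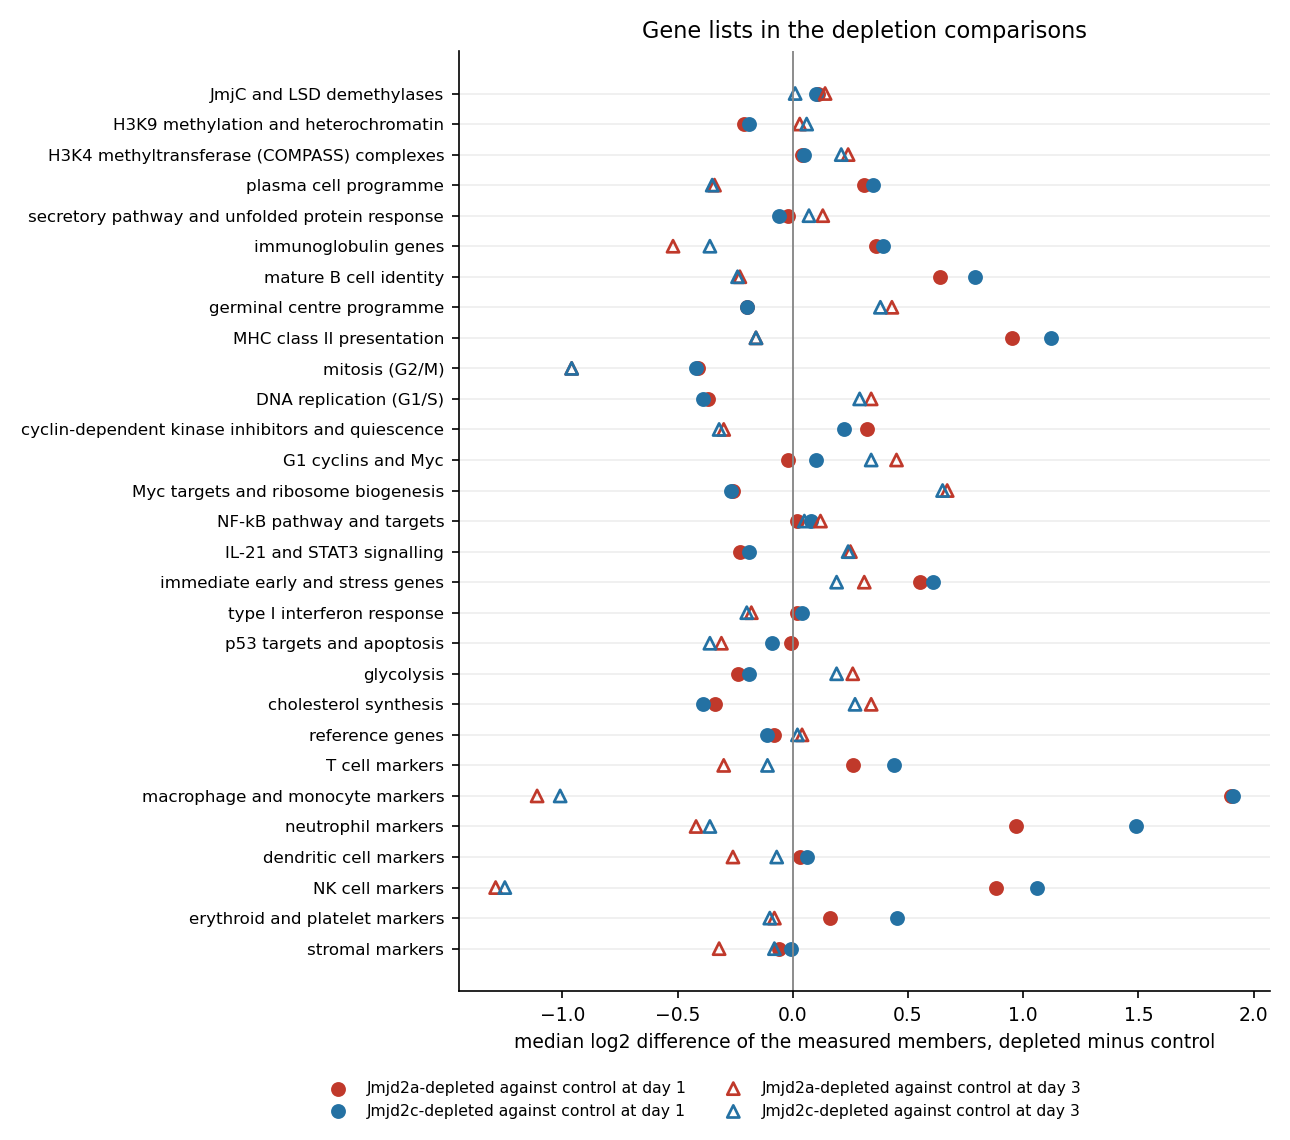
Median log2 difference from the same-day control (x axis) of the 29 gene lists (y axis), with 1 point for each label and day. Mitosis genes lie at -0.41 and -0.42 at day 1 and at -0.96 with both labels at day 3, and Myc targets and ribosome biogenesis genes at -0.26 and -0.27 at day 1 and at 0.67 and 0.65 at day 3.

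Between day 1 and day 3 the control cells raised mitotic genes and lowered genes of ribosome biogenesis. The largest rises were Gzma (4.77 ± 0.27) and Lpl (4.47 ± 0.4), a granzyme and lipoprotein lipase, then 2900026A02Rik (4.32), Gpr34 (4.28), Gzmb (4.25), S100a4 (4.2), Fabp4 (4.01) and C1qb (3.98). The largest falls were Pcp4 (-4.4 ± 0.18), Rgs13 (-3.32 ± 0.18), Maf (-3.11), Serpinb1a (-3.08), Pigr (-3.06), Kdm6b (-3.03) and Xrcc5 (-2.77) and Smad1 (-2.68), a mediator of BMP signalling (limma adjusted p = 2.5e-08 to 1.2e-05 for the rises). By the same test 10741 probe sets changed, 3809 higher and 6932 lower, 633 and 846 of them by at least 2-fold. The count was 6066 or 7014 without day 1 control replicate 1 or 2, and 18044 without day 3 control replicate 1.

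In the control cells all 29 measured mitosis genes rose (29 in the list alone, median 1.26, adjusted p = 4.6e-27), with Ccnb2 (2.24). Of Myc targets and ribosome biogenesis genes 27 of 27 fell with no rise (27 in the list alone), with Srm (-1.19), and these 2 lists passed with an estimated correlation. The median was -0.74 (adjusted p = 4.3e-25). In DNA replication 3 of 30 rose and 20 fell (3 up and 20 down in the list alone), with Cdt1 (-1.03). The median was -0.38 (adjusted p = 1.8e-07, but 0.17 with an estimated correlation). Of the plasma cell programme, 11 of 21 rose and 2 fell (11 up and 2 down in the list alone), with Sec11c (1.14). The median was 0.29 (adjusted p = 0.0012, but 0.31 with an estimated correlation). Of mature B cell genes 12 of 23 rose and 4 fell (14 up and 5 down in the list alone), with Cd79b (0.9) up and Id3 (-1.16) down. The median was 0.32 (adjusted p = 0.023, but 0.38 with an estimated correlation). Of the germinal centre programme 1 of 14 rose and 8 fell (1 up and 9 down in the list alone). The median was -0.54 (adjusted p = 0.0028, but 0.25 with an estimated correlation). Further lists passed, given here by their medians. Kinase inhibitors and quiescence (0.38), p53 targets (0.34) and immunoglobulin genes (0.66) passed upward, with Btg1 (0.71) and Bcl2l11 (1.88) up. Glycolysis (-0.32), cholesterol synthesis (-0.35), the secretory pathway (-0.14), H3K4 methyltransferases (-0.26), the IL-21 and STAT3 list (-0.31) and demethylases (-0.14, but 0.02 with quantile normalization) passed downward, with Slc16a1 (-1.45), Cyp51 (-0.79), Stat3 (-0.83) and Kdm6b (-1.28) down. All of these lost the call with an estimated correlation (adjusted p = 0.081 to 0.35). Other probe sets of Ighm and Iglv1 passed with the opposite sign. Markers of macrophages and monocytes (Vcam1 3.44 among them) and of NK cells rose in the controls over the same days: 15 of 18 rose with no fall (15 in the list alone), and 6 of 9 rose with no fall (8 in the list alone). Their medians were 1.73 (adjusted p = 7.8e-08, but 0.18 with an estimated correlation) and 1.81 (adjusted p = 7.5e-06, but 0.15 with an estimated correlation), in the order named. The remaining 12 lists did not pass. Beside these changes the day 3 controls held replicate 2, with its 18S level of 10.732. Of the list calls, mature B cell genes (adjusted p = 0.053 and 0.091 without day 1 control 2 or day 3 control 1) and demethylases (adjusted p = 0.066 and 0.17 without day 1 control 1 or day 3 control 2) lost the call.

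Of the genes followed throughout, Xbp1 (0.8), Jchain (1.34), Cdkn1b (0.71), Cdkn2c (0.54), Cdkn3 (2.21) and Mki67 (1.26) rose in the control cells. Those that fell were Sdc1 (-1.2), Myc (-1.27), Ccnd2 (-1.02), Bcl6 (-0.57), Bach2 (-0.61), Wdr5 (-0.52) and Nfkbia (-0.11) (largest adjusted p = 0.033), while Prdm1 (0.11), Irf4 (0.23), Pax5 (-0.12) and Kdm4c (-0.05) did not pass (adjusted p = 0.13 to 0.81) and Kdm4a (0.27) rose (adjusted p = 0.041). Another probe set of Pax5 passed with the opposite sign. Without 1 array these gene calls ended or moved by over 1.5 times, Cdkn1b (0.46 without day 3 control 1), Cdkn2c (0.49 and 0.31 without day 1 control 1 or day 3 control 1), Nfkbia (-0.12 to -0.09 without day 1 control 1 or 2 or day 3 control 1 or 2) and Kdm4a (0.26 and 0.28 without day 1 control 1 or 2).

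On the arrays labelled depleted, genes among the largest rises of day 1 fell by day 3, and mitotic genes rose. The largest falls were Fcer2a (-4.81 ± 0.21 and -5.09 ± 0.21), Vcam1 (-4.8 ± 0.25 and -5.06 ± 0.25), Fos (-4.64 and -5.09), Ltb (-4.53 and -4.99) and Csf1r (-3.97 and -4.16) and Slc4a1 (-4.02 and -4.08), with Adgre4 (-4.05) and Mirt1 (-3.88) for the Jmjd2a label and Ackr3 (-4.28) and Acp5 (-4.21) for the Jmjd2c label. The largest rises were Fnbp1l (2.2 ± 0.14 and 2.42 ± 0.14), 2900026A02Rik (2.25 ± 0.18 and 2.22 ± 0.18) and Gzmb (1.97 ± 0.16 and 1.94 ± 0.16), Gbp2 (1.93 and 1.91), Ifitm1 (1.59 and 1.65) and Cxcl10 (1.59 and 1.63), the last 3 being interferon-induced genes. Anxa1 (1.51) and Ccl22 (1.43) for the Jmjd2a label and Cdkn2a (1.88) and Fah (1.75) for the Jmjd2c label completed them (limma adjusted p at most 0.0015). By that test 2527 and 3888 probe sets changed, 1017 and 1472 higher and 1510 and 2416 lower. At least 2-fold, 29 and 44 were higher and 486 and 672 lower. For the Jmjd2a label the count was 950 without its day 1 replicate 1 and 826 or 761 without its day 3 replicate 1 or 2. For the Jmjd2c label it was 2354 or 2163 without day 1 replicate 1 or 2 and 1402 or 1480 without day 3 replicate 1 or 2. In the fit without day 3 control replicate 2 they were 5542 and 7643, and with array weights 5308 and 7479. With quantile normalization the share of higher calls for the Jmjd2c label was 49.3%, against 37.9% as deposited.

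Over the same days, 13 and 17 of 23 fell with no rise (18 and 19 in the list alone) among the mature B cell genes of the arrays labelled depleted, with Cr2 (-3.7 and -3.82). The median was -0.61 and -0.72 (adjusted p = 2.5e-20 and 1.6e-20). Of MHC class II genes 10 of 10 fell with no rise (10 in the list alone), with H2-Ob (-2.22 and -2.5). The median was -0.81 and -1.07 (adjusted p = 2.9e-19 and 1.1e-18). Of mitosis genes, 28 of 29 rose with no fall (28 and 29 in the list alone), with Ccnb2 (1.08 and 1.19). The median was 0.7 and 0.73 (adjusted p = 3.7e-32 and 2.2e-28). Of DNA replication genes 17 and 18 of 30 rose with no fall (26 and 24 in the list alone), with Rrm2 (0.43 and 0.42). The median was 0.35 and 0.29 (adjusted p = 2.7e-16 and 2.4e-11, but 0.039 and 0.069 with an estimated correlation). Of immediate early and stress genes, 0 and 1 of 23 rose and 10 and 12 fell (3 up and 16 down in the list alone), with Fosb (-3.22 and -3.19). The median was -0.49 and -0.58 (adjusted p = 6.2e-13 and 2.4e-11, but 0.045 and 0.069 with an estimated correlation). Of the macrophage and monocyte markers 8 and 10 of 18 fell with no rise (0 and 1 up and 11 and 13 down in the list alone), with Csf1r (-3.97 and -4.16). The median was -1.39 and -1.43 (adjusted p = 5e-14 and 1.1e-10, but 0.065 and 0.11 with an estimated correlation). Of the NK cell markers 5 of 9 fell with no rise (5 and 8 in the list alone), with Klra8 (-1.75 and -1.68). The median was -0.63 and -0.8 (adjusted p = 1.2e-06 and 1.1e-06, but 0.056 and 0.069 with an estimated correlation). Further lists passed, given here by their medians. Myc targets and ribosome biogenesis (0.17 and 0.15), cholesterol synthesis (0.3) and glycolysis (0.21 and 0.18) passed upward with both labels, and with the Jmjd2c label no longer with an estimated correlation (adjusted p = 0.069 to 0.09). Kinase inhibitors and quiescence (-0.21 and -0.17), demethylases (-0.07 and -0.17), the plasma cell programme (-0.13 and -0.17) and T cell (-0.23 and -0.08), erythroid (-0.08 and -0.36) and neutrophil markers (-1.11 and -1.61) passed downward, and all but T cell markers with the Jmjd2a label were lost with an estimated correlation (adjusted p = 0.069 to 0.39). With 1 label alone, immunoglobulin genes (-0.18) and the IL-21 list (0.3) for Jmjd2a and H3K4 methyltransferases (-0.05) for Jmjd2c passed, and not with an estimated correlation (adjusted p = 0.36, 0.056 and 0.56).

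The genes followed throughout gave Cdkn3 (1.14 and 1.08) and Mki67 (0.51 and 0.6) up and Cdkn1b (-0.71 and -0.77) down over time on the arrays labelled depleted. For the Jmjd2c label Irf4 (-0.47), Jchain (-0.56) and Myc (-0.59) fell and Sdc1 (0.37) rose, where the Jmjd2a label gave -0.36, -0.47, -0.26 and 0.32 without passing, and the difference between labels was not tested over time. Values of Kdm4a (0.05 and -0.13), Kdm4c (-0.14 and -0.21), Prdm1 (0.19), Xbp1 (0.01 and 0.05), Pax5 (-0.05 and -0.02), Bcl6 (-0.29), Bach2 (0.1 and 0), Ccnd2 (0.17 and 0.18), Wdr5 (0.07 and 0.12), Cdkn2c (0.45 and 0.33) and Nfkbia (0.01 and 0.02) did not pass (adjusted p = 0.069 to 0.98). Over the same days the median of macrophage markers changed by -1.39 and -1.43. Gene calls that ended or moved by over 1.5 times without 1 array were, with the Jmjd2a label Cdkn1b (-0.75 to -0.52 without day 1 Jmjd2a 1 or day 3 Jmjd2a 1 or 2). With the Jmjd2c label they were Cdkn1b (-0.73 and -0.80 without day 3 Jmjd2c 1 or 2), Irf4 (-0.49 to -0.38 without day 1 Jmjd2c 2 or day 3 Jmjd2c 1 or 2), Jchain (-0.86 to -0.26 without day 1 Jmjd2c 1 or 2 or day 3 Jmjd2c 1 or 2) and Sdc1 (0.31 to 0.39 without day 1 Jmjd2c 1 or day 3 Jmjd2c 1 or 2).

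No probe set passed between the arrays labelled Jmjd2a-depleted and Jmjd2c-depleted on either day, although some did at other settings. By limma with Benjamini-Hochberg adjustment the count was 0 at day 1, with 1081 probe sets at an unadjusted p under 0.05 and a smallest adjusted p = 1, and 0 at day 3, with 2571 and 0.76. It was 6 at day 1 without Jmjd2a replicate 1, and at day 3 it was 26 with array weights and 66 in the fit without control replicate 2. The values of smallest p at day 1 were Rdx (0.34) and Tra2a (0.26) higher and Itih5 (-0.53) and Srpk3 (-0.48) lower with the Jmjd2a label, none of which passed. Those of day 3 were Wdr33 (0.74) and Camk2d (0.59), and Spry4 (-0.48) and Smc1a (-0.58) (adjusted p = 0.85). Across probe sets the median absolute difference was 0.077 at day 1 and 0.101 at day 3, and the 99th percentile 0.374 and 0.487, where the median 95% interval of a difference reached 0.288 to either side. Of the 29 lists, 5 passed camera at day 1 and 6 at day 3, and 0 passed with an estimated correlation or by fry. At day 1 these were the secretory pathway (median 0.04) and cholesterol synthesis (0.04), up, and mature B cell identity (-0.11), MHC class II presentation (-0.16) and NK cell markers (-0.17), down (adjusted p = 0.007 or less, and adjusted p = 0.56 or more with an estimated correlation). At day 3 they were the demethylases (0.07), H3K4 methyltransferases (0.05, -0.02 with quantile normalization), DNA replication (0.05), NF-kB (0.06), interferon (0.08) and cholesterol synthesis (0.06), all up (adjusted p = 0.69 with an estimated correlation). No list member passed over all probe sets, and in the list alone 0 passed at day 1 and 1 kinase inhibitor and 1 T cell marker at day 3. The number of lists was 11 without day 1 Jmjd2a replicate 1 and 8 without day 1 Jmjd2c replicate 1, and at day 3 it was 1 or 2 without Jmjd2a replicate 1 or 2 and 1 without Jmjd2c replicate 1.

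The difference from control changed between the days for many probe sets. In limma, with Benjamini-Hochberg adjustment, the day 3 difference minus the day 1 difference passed for 8264 probe sets with the Jmjd2a label, 5401 up and 2863 down, and for 7879 with the Jmjd2c label, 4800 up and 3079 down. The count of the Jmjd2a label was 14662 without day 3 control replicate 1 and 5277 without day 3 Jmjd2a replicate 2, and that of the Jmjd2c label was 12912 without day 3 control replicate 1. Of Myc targets and ribosome biogenesis genes 27 of 27 rose with no fall (27 in the list alone), the list that passed with an estimated correlation for both labels. The median was 0.94 and 0.98 (adjusted p = 9e-26 and 7.8e-26). The other lists that passed are given by their medians. Downward were macrophage (-2.76 and -2.92), NK cell (-2.28 and -2.3), neutrophil (-1.46 and -1.8), T cell (-0.61 and -0.39), erythroid (-0.43 and -0.48) and dendritic cell markers (-0.3 and -0.33). So were MHC class II (-1.12 and -1.36), mature B cell (-0.96 and -1.3), immediate early (-0.78 and -0.85), immunoglobulin (-0.74 and -0.75), plasma cell (-0.72 and -0.75), kinase inhibitor (-0.72 and -0.6), mitosis (-0.58 and -0.5) and p53 genes (-0.36 and -0.25), and interferon (-0.33) with the Jmjd2c label alone. Upward were DNA replication (0.77 and 0.66), cholesterol synthesis (0.57 and 0.59), glycolysis (0.37 and 0.35), IL-21 and STAT3 (0.47) and germinal centre genes (0.46 and 0.44). Of these, glycolysis with the Jmjd2a label alone passed with an estimated correlation, and the others did not (adjusted p = 0.052 to 0.45). The calls ended for neutrophil markers (Jmjd2a, adjusted p = 0.066 without day 1 Jmjd2a 2), immediate early genes (Jmjd2a, 0.059 without day 3 control 1), interferon (Jmjd2c, 0.22 without day 3 control 1) and germinal centre genes (Jmjd2c, 0.069 without day 3 control 2). Across all contrasts, 18 and 16 of the 29 lists passed camera at day 1, 17 and 18 at day 3, 17 over time in control cells, 18 and 17 over time on the arrays labelled depleted, and 20 and 21 for the change between days. With an estimated correlation 12, 10, 2, 2, 2, 9, 3, 2 and 1 passed, in the same order. By fry's one-direction test, which compares a list with no other genes, 18, 18, 23, 19, 24, 17, 14, 22 and 25 passed.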

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

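The tests of explanations in this part were chosen only after the results were seen, the comparisons with same-day controls and between days before. On the arrays labelled depleted at day 1, 617 and 744 probe sets rose and 6 and 18 fell by at least 2-fold. RNA of cells other than B cells, on its own, was argued against by 17 and 19 risen mature B cell genes with the Jmjd2a and Jmjd2c labels, of which the other cell lists hold 0. RNA of unstimulated spleen cells mixed in would dilute genes of the stimulated cells, and the median fall of cell-cycle genes of -0.39 and -0.4 would need a share of 23.7% and 24.2%. Of the fallen probe sets, 58 and 147 (3.97% and 5.73%) lay beyond that fall by more than their 95% interval, Kif11 at -1.32 and -1.38 among them, where a larger share of other RNA would allow them. Few large falls are part of the pattern itself, so this decides nothing, and a mixture cannot be told apart from other explanations, with the macrophage list at a mean of 7.6 and 7.77 against 5.49 in the controls. Lower RNA quality as read by 18S stays open. Median rises in 581 probe sets at least 2-fold higher with both labels were 1.35 to 1.73 on the day 1 arrays so labelled. On 5 others of low 18S they reached 0.32 over the day 1 controls, but all were of day 3. Selection on B220 would remove most T cells, macrophages and NK cells but not resting B cells, and an effect of the depletion itself stays open and untested.

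The arrays labelled depleted at day 3 correlated more with the day 1 than with the day 3 controls. An exchange of the day labels of the depleted arrays, with little effect of depletion, was argued against by 11170 and 9924 probe sets that differed between the arrays labelled depleted at day 1 and the day 3 controls, for the Jmjd2a and Jmjd2c labels. The arrays labelled depleted at day 3 differed from the day 1 controls in 75 and 72 probe sets. Counts between like cultures were unknown, so day 1 arrays without an effect stay open. So do slower progress of the culture under depletion, another effect of depletion, and exchanged labels with an effect of depletion, all untested.

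The change between days differed from that of the controls for 8264 probe sets with the Jmjd2a label and 7879 with the Jmjd2c label. With the Jmjd2a label the largest of these were Pcp4 at 4.59, Rgs13 at 3.55, Pigr at 3.32, Kdm6b at 3 and Maf at 2.89, and Vcam1 at -8.25, C1qb at -7.18, Slc40a1 at -6.08, Csf1r at -5.72 and Mrc1 at -5.16. With the Jmjd2c label they were Pcp4 at 4.53, Rgs13 at 3.58, Pigr at 3.35, Serpinb1a at 3.01 and Kdm6b at 3.01, and Vcam1 at -8.5, C1qb at -7.65, Slc40a1 at -6.26, Csf1r at -5.91 and Mrc1 at -5.81.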

How the results depend on the processing

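Tests on arrays of the other day, and fits without day 3 control replicate 2 for contrasts not using it, were chosen after seeing the data, the other settings before. Groups of 2 arrays left no spread to test a single array against, and the lone array of a group was assumed to vary like the other groups. The cause of differences between settings was not tested.

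With array weights the number of changed probe sets became 6378 (Jmjd2a at day 1), 8386 (Jmjd2c at day 1), 5711 (Jmjd2a at day 3), 4114 (Jmjd2c at day 3), 5308 (time with Jmjd2a), 7479 (time with Jmjd2c), 26 (Jmjd2a against Jmjd2c at day 3), 5667 (calls shared by both labels at day 1) and 3878 (calls shared at day 3). Without the intensity trend it was 2097 (Jmjd2a at day 1), 1593 (time with Jmjd2a) and 1910 (calls shared by both labels at day 1). With one probe set per gene it was 3180 (Jmjd2c at day 1), 5049 (Jmjd2a at day 3), 4001 (Jmjd2c at day 3), 5627 (time in control), 2537 (time with Jmjd2c), 4684 (the change between days with Jmjd2a), 4561 (the change between days with Jmjd2c) and 3644 (calls shared at day 3), out of fewer tests. At an adjusted p under 0.10 it was 3820 (time with Jmjd2a). With a floor of 1.5-fold it was 1446 (Jmjd2a at day 1), 1948 (Jmjd2c at day 1), 4064 (Jmjd2a at day 3), 2730 (Jmjd2c at day 3), 5176 (time in control), 1296 (time with Jmjd2a), 1871 (time with Jmjd2c), 1313 (calls shared by both labels at day 1) and 2480 (calls shared at day 3). Replicate number as a block moved no count by more than 1.5 times (3536 for Jmjd2a at day 1). Over all settings that kept all arrays, 81 counts of changed probe sets stayed within 1.5 times.

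The number of lists past the test with an estimated correlation was 10 (Jmjd2c at day 1), 2 (Jmjd2a at day 3), 2 (Jmjd2c at day 3), 2 (time in control), 9 (time with Jmjd2a), 3 (time with Jmjd2c), 0 (Jmjd2a against Jmjd2c at day 1), 0 (Jmjd2a against Jmjd2c at day 3), 2 (the change between days with Jmjd2a) and 1 (the change between days with Jmjd2c). For Jmjd2a against Jmjd2c at day 3 it was 1 with quantile normalization and 0 without dim probe sets. Quantile normalization turned the sign of genes that had not passed: Pax5 (-0.053 for Jmjd2a at day 1, -0.087 for Jmjd2a at day 3, -0.067 for Jmjd2c at day 3, 0.026 for time in control, 0.09 for time with Jmjd2c), Kdm4c (-0.042 for Jmjd2a at day 3, -0.066 for Jmjd2c at day 3, 0.127 for time in control), Prdm1 (-0.136 for Jmjd2a at day 3), Nfkbia (-0.001 for Jmjd2a at day 3, -0.008 for time with Jmjd2a) and Xbp1 (-0.023 for time with Jmjd2a). Among named genes 6 values lost and 11 gained a call in settings that kept all arrays, and 1548 kept their sign and side of the threshold.

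Leaving out arrays in turn gave ranges of 1043 to 6704 (Jmjd2a at day 1), 1829 to 8449 (Jmjd2c at day 1), 6066 to 18044 (time in control), 1000 to 2688 (calls shared by both labels at day 1), 761 to 5542 (time with Jmjd2a), 0 to 6 (Jmjd2a against Jmjd2c at day 1), 1402 to 7643 (time with Jmjd2c), 4240 to 17389 (Jmjd2a at day 3), 2941 to 12578 (Jmjd2c at day 3), 5277 to 14662 (the change between days with Jmjd2a), 5362 to 12912 (the change between days with Jmjd2c), 2866 to 11831 (calls shared at day 3) and 0 to 66 (Jmjd2a against Jmjd2c at day 3), those of contrasts without day 3 controls including the fit without day 3 control replicate 2, in which shared calls were not counted. Numbers of lists ranged over 6 to 11 (Jmjd2a against Jmjd2c at day 1) and 1 to 6 (Jmjd2a against Jmjd2c at day 3). Kdm4c as the target of Jmjd2c at day 3 ranged over -0.17 to 0.234. Genes that had not passed turned sign: Prdm1 (-0.232 to 0.157 for Jmjd2a at day 1, -0.002 to 0.387 for time with Jmjd2a, -0.409 to 0.062 for Jmjd2c at day 3, -0.128 to 0.343 for time in control, -0.187 to 0.284 for Jmjd2a at day 3), Pax5 (-0.203 to 0.215 for Jmjd2a at day 1, -0.263 to 0.155 for time with Jmjd2a, -0.147 to 0.105 for time with Jmjd2c, -0.124 to 0.127 for Jmjd2c at day 3), Kdm4a (-0.03 to 0.124 for time with Jmjd2a), Xbp1 (-0.023 to 0.035 for time with Jmjd2a, -0.031 to 0.125 for time with Jmjd2c), Nfkbia (-0.012 to 0.024 for time with Jmjd2a), Bach2 (-0.037 to 0.029 for time with Jmjd2c) and Kdm4c (-0.059 to 0.345 for Jmjd2a at day 3, -0.17 to 0.234 for Jmjd2c at day 3, -0.248 to 0.156 for time in control).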

Other observations

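The comparisons with controls of the other day and the test of dim probe sets were chosen after seeing the data, the comparison of the targeted genes with same-day controls before. Against the day 1 controls, arrays labelled depleted at day 3 differed in 75 (Jmjd2a) and 72 (Jmjd2c) probe sets by limma with Benjamini-Hochberg adjustment. At an unadjusted p under 0.05, 2258 and 4022 did. Among the largest were Lpl (2.51 and 2.65 log2, adjusted p = 0.034 and 0.024), Gzma (2.44 and 2.48), Gzmb (2.13 and 2.27), S100a4 (2.06 and 2), C1qb (2.02 and 2.15) and Fnbp1l (1.74 and 1.85), which rose in the controls by 4.47, 4.77, 4.25, 4.2, 3.98 and 3.91 from the same day 1 controls. Lower were Srsf11 (-1.1) and Pnn (-0.85) with the Jmjd2a label, which changed by 0.29 and -0.04 in the controls, and Malat1 (-1.03 and -1.15), Asxl2 (-0.97 and -0.98) and Ddx6 (-0.85 and -0.9), which changed by -0.77, -0.66 and -0.19.

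The transcripts of the targeted genes were not lower past the test on the arrays labelled depleted. Probe sets too dim to measure them were argued against by the mean levels of Kdm4a and Kdm4c, which stood at the 81.1 and 79.9 percentile of all probe sets. Cells without depletion in the same culture could supply the transcript. The share of depleted cells was not measured, so this stays open beside a depletion that acts on the protein or did not act.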
